A study of Homo sapiens with 24 samples.

How the data were processed

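RNA of N/TERT1 keratinocytes had been measured on Illumina bead arrays of 47304 probes, 24 arrays in 6 groups of 4. The groups were taken from the sample labels, and each array is named by its group and replicate number. The submitters' processing notes name GenomeStudio; its version and settings are not given in the sources used here.

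The series matrix deposited by the authors holds a linear fluorescence intensity per probe and array, from -67.97 to 68803.6. Values below 0 and unequal distributions across arrays show that the background had been subtracted on each array and that arrays had not been normalized to one another. A further table, per the file headers, gives a signal and a detection p-value for each probe and array, the p-value comparing the probe with the negative controls of that array. The sources do not describe how the signals of that table, deposited as non-normalized, were made. Read from their values, they appear to have been normalized towards the first undifferentiated array, with intensity values under 40 set to 40, which holds for 65.7% of them. On 505 probes at that floor the series matrix had a signal over 200 on at least 1 array, and 338 of these were tested features. Their signal on the first undifferentiated array was at most 19.95 in the series matrix. All 377 probes over 200 on day 6 replicate 1 and at or under 20 on that first array were at the floor. Among tested genes, the 505 probes stood for 22 of 46 cornified envelope, 4 of 19 spinous and 4 of 19 stress keratin genes, but 0 of 32 mitosis genes. The design written in advance had taken the table named as non-normalized for the raw signals. The series matrix intensities with the detection p-values were used instead, and the normalized table served only as an alternative.

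Probes were named from the annotation table supplied for the series matrix, which lists 1 gene symbol for 30102 probes, several for 8 and none for 17194. Symbols were compared with the names in the RefSeq annotation of assembly GRCh38.p14, used here for names alone, and 0 changed. Probes without a single listed symbol were tested but never named. Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits the background from the detection p-values, adds an offset of 16, quantile-normalizes and takes log2. Probes with detection p under 0.01 on at least 4 of the 24 arrays were kept (14304), and where a gene had several, the brightest over all arrays stood for it (2155 others left out). This gave 12149 features, 9034 with a symbol and 3115 without. No array was left out.

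All 6 groups entered a single lmFit and eBayes fit, and each comparison was a two-sided contrast with Benjamini-Hochberg adjustment over the 12149 features. Features with adjusted p under 0.05 are called past the threshold. The interaction is the EGBG effect in the presence of SDSM minus the EGBG effect without it. A gene is detected on an array when its detection p is under 0.01. Bounds set the mean of the brighter group against the mean, over the arrays of the undetected group, of the lowest normalized signal among detected probes or the gene's own signal, whichever was higher.

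There were 28 gene lists with 860 entries, of which 3 carried another current symbol and 664 were tested. All 28 are named with their results in the comparison of day 6 with undifferentiated cells; in the others, lists that are not described were tested and enter the counts only. The melanocyte list, of 10 genes, had 2 tested members. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the lists of a comparison. Members were also counted with p-values adjusted over the list alone.

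Genes were named by a rule. In each comparison they are AMD1, ODC1, SRM, SMS, SAT1, OAZ1, AZIN1, SMOX and PAOX, where measured; the 6 largest rises and 6 largest falls past the threshold whose 4 and 4 arrays did not overlap; and, for each list described, up to 4 members past the threshold with the largest change, or up to 2 of the brightest where none passed. The interaction takes the 4 largest differences of either sign. Genes named this way for day 6 against undifferentiated or for EGBG against day 6 could be followed through the other comparisons.

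Comparisons that share day 6 arrays were also computed with those arrays divided 2 and 2, and beside 100 simulations of unchanged groups. For genes moved back by SDSM, the EGBG arrays were divided 2 and 2 in the same way. Each comparison of 8 arrays was refitted for all 35 divisions of them into 4 and 4. The procedure was tested on 12149 simulated genes, set up as EGBG against day 6. It recovered 32% of 50 genes changed by a log2 of 0.5, 86% at 1 and 100% at 2 and at 4, with 9 false calls. The genes varied independently, so the 0 unchanged lists called among 21 tell little.

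The alternatives were no background correction (signals under 1 set to 1, pseudocount 16, then quantile normalization), median scaling, the series matrix without normalization, no detection filter, detection in a whole group, all detected probes, a replicate block, only the groups compared, array weights, an estimated correlation and each array left out in turn. Chosen after seeing the data were the authors' normalized table, leaving out day 6 replicates 1 and 3 (array weights 0.328 and 0.396, the lowest), and the first axis of the within-group residuals, which holds 29.5% of the residual variance, as a covariate. Array chip as a term was not run, since the columns do not give it.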

Results

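Gene expression was measured in N/TERT1 cells, an immortalized human keratinocyte line that differentiates when calcium is raised. There were 24 Illumina bead arrays of total RNA, 4 in each of 6 groups. The undifferentiated cells grew in medium with 0.3 mM calcium, and the remaining groups were taken 6 days after a switch to 1.2 mM calcium. At day 3 those cells received nothing, 50 µM EGBG, 1 mM spermidine/spermine, EGBG with spermidine/spermine, or 1 mM putrescine. EGBG (ethylglyoxal bis(guanylhydrazone)) blocks AMD1, the enzyme that supplies the aminopropyl groups from which spermidine and spermine are built out of putrescine. Whether 1 mM is the dose of each of spermidine and spermine or of the mixture is ambiguous in the labels. In the text, SDSM stands for spermidine/spermine, PUT for putrescine, and day 6 alone for differentiated cells that received no compound.

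Each array detected 10348 to 13089 of the 47304 probes, with a median of 11529.5, and its mean background-subtracted signal lay between 345 and 637 intensity units. Within groups, arrays correlated at r of at least 0.965 across genes, which are not independent replicates. Arrays of SDSM and of EGBG plus SDSM reached 0.990 with arrays of another group, above the 0.988 within either. The limit on precision is the number of arrays, 4 per group. The series record calls them biological replicates and does not say whether they came from separate cultures, so the p-values measure only the spread between these samples. Changes are log2 differences between group means ± SE, with 4 arrays on each side and the spread estimated from all 24 arrays, and 12149 features were tested. The genes with the largest changes were chosen among those whose 4 arrays of either group did not overlap, so that all 4 showed the direction given. A gene undetected on every array of a group has only a bound there, given as at least N-fold against the lowest detected signal, and list medians that change with such genes at their bound are followed by that value, except in the interaction. Where a gene was detected on fewer than all arrays of a group, the number and group follow its value. The rank of genes of both kinds rests partly on background. Gene lists were fixed before the data were examined, counts of members are of those measured, and medians are of log2 changes.

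After 6 days in raised calcium, gene lists of the outer epidermis were higher and those of dividing and basal cells lower, the latter only with camera's preset correlation. Calcium and time in culture changed together and are not separated here. The largest rises were in FLG (8.43 ± 0.30, 1 of 4 undifferentiated), the precursor of the moisture-binding filaggrin, KRT1 (8.27 ± 0.33, 1 of 4 undifferentiated), the keratin of suprabasal cells, LORICRIN (8.02 ± 0.36, 2 of 4 undifferentiated), the main protein of the cornified envelope, SPRR2G (8.02 ± 0.32, 2 of 4 undifferentiated), and the late cornified envelope genes LCE3D (7.60 ± 0.28, 3 of 4 undifferentiated) and LCE3E (7.58 ± 0.24, 1 of 4 undifferentiated). The largest falls were in the protease inhibitor TFPI2 (at least 21.2-fold), the forkhead factor FOXA2 (at least 33.6-fold), VIM (-4.43 ± 0.23), which encodes the mesenchymal filament vimentin, CDC20 (-4.30 ± 0.27), an activator of mitotic exit, the metallothionein MT1E (-4.04 ± 0.22) and KRT15 (-4.01 ± 0.25, 2 of 4 day 6), a keratin of basal cells. This comparison asks which genes mark differentiation before any compound is added. Probes of the LCE, SPRR2, MT1, PSG and DEFB103 families, whose members are close paralogs, leave the member a value belongs to uncertain throughout.

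Of the cornified envelope genes, 46 of 46 rose and 0 fell (the same adjusted over the list alone), with a median of 4.71 (4.39 at bounds) and camera adjusted p = 5e-34. Among spinous layer genes, 18 of 19 rose and 0 fell (the same adjusted over the list alone), among them the desmosomal cadherins DSC1 (7.47 ± 0.23, 1 of 4 undifferentiated) and DSG1 (at least 29.6-fold) and the secreted SBSN (7.09 ± 0.24). The list had a median of 3.43 and camera adjusted p = 5.52e-14. For barrier lipid synthesis, 23 of 25 rose and 0 fell (the same adjusted over the list alone), with a median of 2.84 (2.26 at bounds) and camera adjusted p = 1.53e-15. Among its members were ALOX12B (6.43 ± 0.25, 1 of 4 undifferentiated), a lipoxygenase of the lipid envelope, and CYP4F22 (at least 18.1-fold). Epidermal proteases and inhibitors had a median of 3.27 and camera adjusted p = 4.51e-18. In this list, 23 of 24 rose and 0 fell (the same adjusted over the list alone), such as KLK7 (6.40 ± 0.20), a kallikrein that sheds corneocytes, SERPINB3 (6.90 ± 0.18, 2 of 4 undifferentiated) and the filaggrin-processing protease ASPRV1 (at least 55-fold). Differentiation transcription factors had a median of 1.76 (1.43 at bounds) and camera adjusted p = 1.31e-08. Gene by gene, 16 of 22 rose and 1 fell (18 and 1 adjusted over the list alone), including HOPX (6.99 ± 0.21), RORA (at least 16.6-fold), GRHL1 (at least 9.13-fold) and KLF4 (3.42 ± 0.21). In the list of stress keratins and antimicrobial genes, 18 of 19 rose and 1 fell (the same adjusted over the list alone), with a median of 3.53 and camera adjusted p = 2.94e-12. S100A7 (6.93 ± 0.35), the antimicrobial psoriasin, SLPI (5.66 ± 0.31) and IL36RN (at least 35-fold) rose.

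Lists of the cell cycle and growth were lower, though not with an estimated correlation. In the mitosis list 0 of 32 rose and 30 fell (the same adjusted over the list alone), with a median of -1.78 (-1.28 at bounds) and camera adjusted p = 7.71e-10, adjusted p = 0.211 with an estimated correlation, and CCNB2 (-3.61 ± 0.28, 2 of 4 day 6) and TOP2A (-3.27 ± 0.23, 1 of 4 day 6) fell along with CDC20. For DNA replication 2 of 23 rose and 14 fell (the same adjusted over the list alone), with a median of -0.79 (-0.71 at bounds) and camera adjusted p = 0.00977, adjusted p = 0.25 with an estimated correlation. CDC45 (at least 3.20-fold) and GINS2 (at least 2.98-fold), parts of the replicative helicase, fell. Ribosome biogenesis genes had a median of -1.04 and camera adjusted p = 4.06e-06, adjusted p = 0.177 with an estimated correlation. Counted singly, 0 of 23 rose and 20 fell (0 and 21 adjusted over the list alone), such as FBL (-2.12 ± 0.13) and NOP56 (-1.91 ± 0.20) of the box C/D particles that methylate ribosomal RNA. Basal and hemidesmosome genes had a median of -0.77 and camera adjusted p = 0.00977, adjusted p = 0.191 with an estimated correlation. Of its members, 3 of 22 rose and 16 fell (the same adjusted over the list alone), among them EGFR (-1.83 ± 0.24) and ITGA3 (-1.74 ± 0.14). The interferon list was mixed, with IFI27 (5.03 ± 0.59) higher and HERC5 (-2.98 ± 0.21, 1 of 4 day 6) and IFIT1 (-2.62 ± 0.35) lower; 6 of 32 rose and 19 fell (the same adjusted over the list alone), with a median of -0.82 (-0.75 at bounds) and camera adjusted p = 0.0384, adjusted p = 0.612 with an estimated correlation. Amino acid response genes, targets of ATF4, had a median of -0.68 and camera adjusted p = 0.0451, adjusted p = 0.612 with an estimated correlation. By gene, 4 of 33 rose and 20 fell (5 and 20 adjusted over the list alone), SLC7A5 (-2.34 ± 0.24) and TRIB3 (-2.26 ± 0.33) falling and NUPR1 (5.08 ± 0.30, 1 of 4 undifferentiated) rising.

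Cholesterol synthesis had a median of 0.99 (0.84 at bounds) and camera adjusted p = 0.00321, adjusted p = 0.25 with an estimated correlation, with SC5D (3.09 ± 0.19) up. Glycolysis and hypoxia genes had a median of 0.60 and camera adjusted p = 0.00119, adjusted p = 0.21 with an estimated correlation, with HK2 (2.08 ± 0.18) up. Autophagy and lysosome genes had a median of 0.90 (0.85 at bounds) and camera adjusted p = 0.000131, with GPNMB (4.54 ± 0.31, 1 of 4 undifferentiated) up. The heat shock list had a median of 0.39 and camera adjusted p = 0.0162, with the small chaperones HSPB8 (at least 12.1-fold) and CRYAB (4.43 ± 0.27, 3 of 4 undifferentiated) up. Lists that did not pass were the unfolded protein response (median -0.57, adjusted p = 0.083), p53 targets (median -0.12, adjusted p = 0.835), NRF2 targets (median -0.17, adjusted p = 0.273), immediate early genes (median -0.07, adjusted p = 0.723), cytokines and NF-kB targets (median -0.19 (-0.02 at bounds), adjusted p = 1), oxidative phosphorylation (median -0.14, adjusted p = 0.714), cytosolic ribosomal proteins (median -0.09, adjusted p = 0.467) and metallothioneins (median -1.52, adjusted p = 0.394). Markers of other cell types did not pass either, with median 1.08 (0.74 at bounds), adjusted p = 0.221 for melanocytes, median 0.03, adjusted p = 0.913 for fibroblasts and median -0.30, adjusted p = 0.835 for immune cells. Single markers of other cells moved both ways: PMEL of melanocytes (at least 2.97-fold), COL1A1 of fibroblasts (2.17 ± 0.27) and CD207 of Langerhans cells (at least 8.46-fold) rose, and ACTA2 of fibroblasts (-1.42 ± 0.15), CD14 (-0.87 ± 0.31) and HLA-DRA (-0.47 ± 0.15) of immune cells fell.

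Polyamine genes did not pass as a list at day 6. ODC1, which makes putrescine, fell (-1.66 ± 0.19), as did the spermidine synthase SRM (-0.85 ± 0.17), the spermine synthase SMS (-0.92 ± 0.22), the oxidases SMOX (-0.70 ± 0.21, 2 of 4 day 6) and PAOX (at least 1.99-fold) and AZIN1 (-1.87 ± 0.15), which frees ornithine decarboxylase from its antizyme. AMD1 was at 0.57 ± 0.32 (adjusted p = 0.134), the acetyltransferase SAT1 at 0.07 ± 0.13 and the antizyme OAZ1 at -0.11 ± 0.13, and none of these passed. ARG1, which makes ornithine, rose at least 71.1-fold. Of the polyamine metabolism and transport list, 1 of 25 rose and 11 fell (the same adjusted over the list alone), with a median of -0.23 and camera adjusted p = 0.221. The rotation test fry, which asks whether a list's genes move one way on balance and compares them with no other genes, gave adjusted p = 6.88e-11 for a fall.

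In all, 7001 of 12149 features passed at day 6, 2894 higher (1508 at least 2-fold) and 4107 lower (1848 at least 2-fold). Of the 28 lists, 16 passed with camera's preset correlation, 10 higher and 6 lower, and 8 of them also with an estimated correlation, namely cornified envelope, spinous, barrier lipid, protease, transcription factor, stress keratin, heat shock and autophagy genes. The calls that ended without 1 array were those of the amino acid response (ATF4) list without undifferentiated replicate 1, 2 or 4 or day 6 replicate 1 or 2 (adjusted p up to 0.109), CD14 without undifferentiated replicate 2 or 4 (adjusted p up to 0.0767) and the interferon response list without undifferentiated replicate 2 or 4 or day 6 replicate 4 (adjusted p up to 0.0992).

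**Figure D1:**
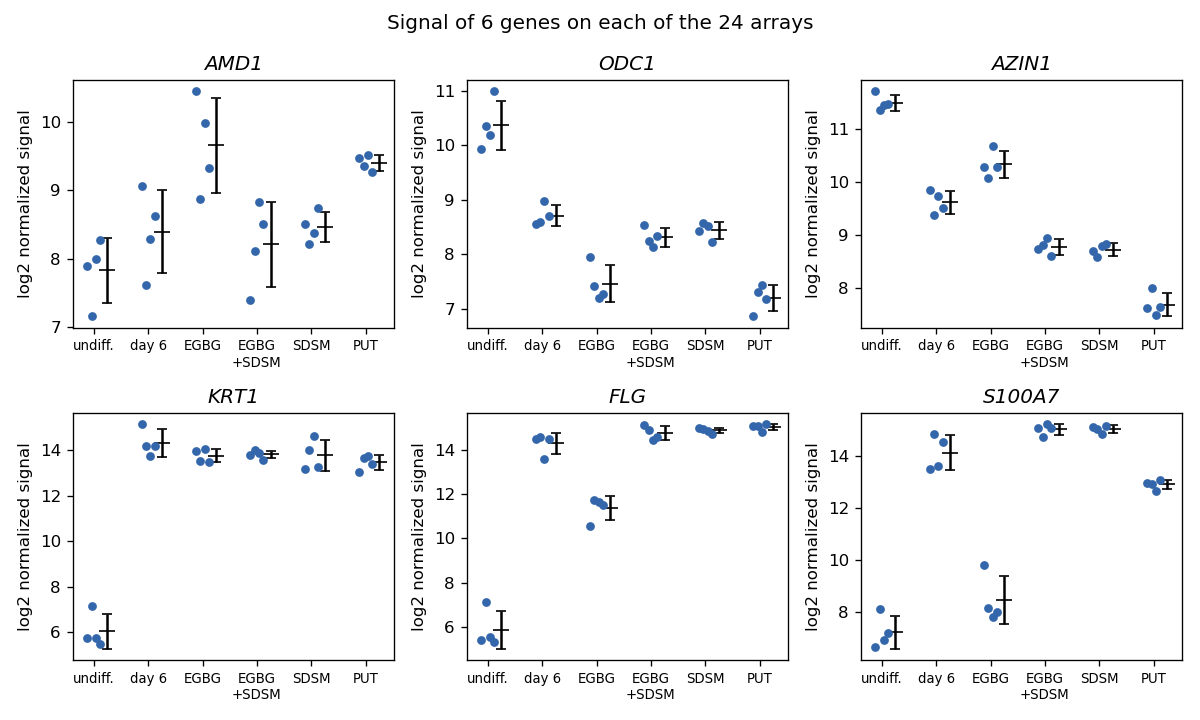
Log2 normalized signal of 6 genes on each of the 24 arrays, by group (points, 1 per array; the dash and bars beside them are the mean and SD of 4 arrays). FLG and S100A7 were lower with EGBG than at day 6 and higher again when SDSM was added, while KRT1 with EGBG differed from day 6 by a log2 of -0.54 ± 0.33, which did not pass the test.

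With the AMD1 inhibitor EGBG added at day 3, genes of late keratinocyte differentiation were lower. The largest falls were in S100A7 (-5.70 ± 0.35), SPRR2B (at least 20.5-fold), SPRR2C (-4.83 ± 0.24), CRCT1 (-4.64 ± 0.23), a cysteine-rich protein of the cornified layer, LCE3A (at least 11.2-fold) and SERPINA12 (-4.57 ± 0.23, 1 of 4 EGBG), the serpin vaspin. FLG2 (-4.35 ± 0.30, 3 of 4 EGBG), a relative of filaggrin, and LCE3E (-4.32 ± 0.24) fell too. The largest rises were in COQ8A (at least 6.48-fold), needed to make coenzyme Q, HERC5 (3.61 ± 0.21, 1 of 4 day 6), the ligase that attaches ISG15, TXNIP (3.17 ± 0.55), a glucose-responsive inhibitor of thioredoxin, PLD6 (3.02 ± 0.20, 3 of 4 day 6), a mitochondrial phospholipase, the adhesion protein EPCAM (2.86 ± 0.23) and the inositol phosphatase INPP5D (2.72 ± 0.20). This comparison asks which genes depend on AMD1 activity during differentiation.

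Of the cornified envelope genes, 0 of 46 rose and 44 fell (0 and 45 adjusted over the list alone), with a median of -3.14 and camera adjusted p = 2e-36. Stress keratins and antimicrobial genes had a median of -1.79 and camera adjusted p = 6.41e-12. In this list, 0 of 19 rose and 17 fell (0 and 18 adjusted over the list alone), among them IL36RN (-4.25 ± 0.18), IL36G (-3.995 ± 0.29, 1 of 4 EGBG) and S100A9 (-3.30 ± 0.35), a subunit of calprotectin. Barrier lipid synthesis had a median of -1.69 (-1.39 at bounds) and camera adjusted p = 4.73e-17. Gene by gene, 0 of 25 rose and 23 fell (the same adjusted over the list alone), including CYP4F22 (-3.70 ± 0.25, 3 of 4 EGBG) and the lipase LIPM (-2.87 ± 0.19). Among proteases and inhibitors 0 of 24 rose and 19 fell (the same adjusted over the list alone), with a median of -1.69 (-1.40 at bounds) and camera adjusted p = 1.87e-16. KLK6 (-3.51 ± 0.30), KLK9 (-3.16 ± 0.29, 1 of 4 EGBG) and SPINK7 (-3.13 ± 0.26, 3 of 4 EGBG) fell most.

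Genes of the spinous layer had a smaller median change. There 0 of 19 rose and 7 fell (the same adjusted over the list alone), with a median of -0.54 (-0.32 at bounds) and camera adjusted p = 0.00425, adjusted p = 0.216 with an estimated correlation. Without day 6 replicate 1 that median was -0.28. CALML5 (-4.33 ± 0.31), a calcium-binding protein of late layers, GJB6 (-2.03 ± 0.18) and DSC1 (-1.44 ± 0.23) fell, whereas KRT1 was at -0.54 ± 0.33 (adjusted p = 0.206). Transcription factors of differentiation had a median of -0.44 (-0.31 at bounds) and camera adjusted p = 0.000463, adjusted p = 0.151 with an estimated correlation. PRDM1 (-2.49 ± 0.23), RORA (-1.90 ± 0.21) and OVOL1 (at least 2.53-fold) fell, and the receptor NOTCH1 rose (1.79 ± 0.30). Singly, 1 of 22 rose and 10 fell (1 and 12 adjusted over the list alone).

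Lists of signalling, inflammation and metabolism were lower as well, with an estimated correlation only metallothioneins. Of the immediate early genes, 1 of 28 rose and 20 fell (1 and 21 adjusted over the list alone), with a median of -0.92 (-0.72 at bounds) and camera adjusted p = 4.21e-08, adjusted p = 0.1 with an estimated correlation. They included PHLDA1 (-3.80 ± 0.22), the EGF receptor ligand HBEGF (-2.65 ± 0.34) and DUSP6 (-1.84 ± 0.23). Cytokines and NF-kB targets had a median of -0.93 (-0.42 at bounds) and camera adjusted p = 4.37e-05, adjusted p = 0.134 with an estimated correlation. Counted singly, 0 of 18 rose and 10 fell (the same adjusted over the list alone), such as the prostaglandin synthase PTGS2 (-4.15 ± 0.33, 2 of 4 EGBG) and IL1A (-2.69 ± 0.29). The interferon list had a median of -0.90 (-0.40 at bounds) and camera adjusted p = 0.000366, adjusted p = 0.274 with an estimated correlation. Of its members, 3 of 32 rose and 20 fell (4 and 21 adjusted over the list alone), SAMD9 (-2.60 ± 0.18) and IFI27 (-2.19 ± 0.59) falling while HERC5 rose. Amino acid response genes had a median of -0.67 (-0.60 at bounds) and camera adjusted p = 3.06e-06, adjusted p = 0.207 with an estimated correlation. By gene, 1 of 33 rose and 19 fell (1 and 22 adjusted over the list alone), such as ASNS (-2.69 ± 0.40), which makes asparagine, and PSAT1 (-2.30 ± 0.51) of serine synthesis. Glycolysis and hypoxia genes had a median of -0.57 and camera adjusted p = 1.99e-05, adjusted p = 0.1 with an estimated correlation. In this list, 3 of 31 rose and 17 fell (the same adjusted over the list alone), SLC2A3 (-3.18 ± 0.18) and VEGFA (-2.12 ± 0.28) among them. Metallothioneins had a median of -1.76 (-1.63 at bounds) and camera adjusted p = 2.53e-05. Gene by gene, 0 of 6 rose and 5 fell (the same adjusted over the list alone), MT2A (-2.82 ± 0.50) and MT1E (-1.94 ± 0.22) included.

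The ribosome biogenesis, oxidative phosphorylation, NRF2, p53 target and DNA replication lists, by contrast, were higher, though none with an estimated correlation. In ribosome biogenesis 19 of 23 rose and 0 fell (the same adjusted over the list alone), with a median of 0.70 and camera adjusted p = 2.64e-07, adjusted p = 0.1 with an estimated correlation, led by RRP12 (2.04 ± 0.18) and RRS1 (1.57 ± 0.20). Oxidative phosphorylation had a median of 0.41 and camera adjusted p = 2.6e-05, adjusted p = 0.198 with an estimated correlation. Counted singly, 23 of 44 rose and 0 fell (the same adjusted over the list alone), such as ATP5MC1 (1.16 ± 0.17). NRF2 targets had a median of 0.68 and camera adjusted p = 0.000366, adjusted p = 0.1 with an estimated correlation. Of its members, 16 of 21 rose and 2 fell (17 and 3 adjusted over the list alone). NQO1 (2.13 ± 0.22) rose and HMOX1 (-2.96 ± 0.27) fell. Among p53 targets, 11 of 24 rose and 2 fell (the same adjusted over the list alone), with a median of 0.33 and camera adjusted p = 0.0161, adjusted p = 0.0727 with an estimated correlation. RRM2B (2.48 ± 0.18, 1 of 4 day 6) and SESN1 (2.34 ± 0.19, 3 of 4 day 6) rose while TP53I3 fell (at least 7.37-fold). DNA replication genes had a median of 0.47 (0.29 at bounds) and camera adjusted p = 0.0161, adjusted p = 0.266 with an estimated correlation. By gene, 12 of 23 rose and 2 fell (the same adjusted over the list alone), the sliding clamp PCNA (1.33 ± 0.18) and the thymidylate synthase TYMS (1.14 ± 0.15) rising most. The mitosis list did not pass (median -0.14 (0.00 at bounds), adjusted p = 0.355). Neither did cytosolic ribosomal proteins (median 0.14, adjusted p = 0.165), heat shock (median 0.08, adjusted p = 0.206), the unfolded protein response (median -0.10, adjusted p = 0.135), autophagy (median -0.19, adjusted p = 0.583) or the markers of melanocytes (median -0.24 (-0.13 at bounds), adjusted p = 0.571), fibroblasts (median -0.63 (-0.36 at bounds), adjusted p = 0.825) and immune cells (median 0.36 (0.00 at bounds), adjusted p = 0.637).

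Within the polyamine pathway AMD1 itself rose (1.26 ± 0.32, adjusted p = 0.0027), from a mean log2 signal of 8.40 ± 0.61 to 9.66 ± 0.69 (SD, n = 4), and AZIN1 (0.71 ± 0.15) and SRM (0.62 ± 0.17) rose with it. ODC1 (-1.25 ± 0.19), OAZ1 (-0.83 ± 0.13), SAT1 (-0.50 ± 0.13) and ARG1 (-4.50 ± 0.26) fell, and SMOX fell at least 1.11-fold, detected on 2 of 4 day 6 arrays. SMS was at -0.13 ± 0.22 and did not pass, and PAOX was undetected in both groups. The list as a whole had a median of -0.26 (-0.12 at bounds) and camera adjusted p = 0.0876. By gene, 6 of 25 rose and 10 fell (the same adjusted over the list alone); fry's test of movement in either direction gave adjusted p = 1.04e-21.

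Against day 6 alone, EGBG changed 4736 features, 2590 upward (545 at least 2-fold) and 2146 downward (931 at least 2-fold). Of the 28 lists 19 passed, 5 higher and 14 lower, and 5 of them also with an estimated correlation, namely cornified envelope, barrier lipid, protease, stress keratin and metallothionein genes. In the authors' normalized table, where values stop at a floor, 36.8% of the calls were higher, against 54.7% here. Leaving out 1 array ended the calls of SMOX without day 6 replicate 1 (adjusted p up to 0.0583).

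The genes that EGBG changed were set against their change with differentiation. Of the 4736, 3692 (78.0%) had the opposite sign, and of 3547 that passed in both comparisons 2957 (83.4%) were opposite. There were 1346 raised by differentiation and lowered by EGBG, and 1611 the reverse. Another 390 fell and 200 rose in both. The basal list was lower in both (EGBG median -0.345, camera adjusted p = 0.0233, 0.207 with an estimated correlation). Both comparisons use the same day 6 arrays, which alone forces a negative relation. With the day 6 arrays divided between them, the covariance across genes was -0.440 (-0.468 to -0.397 over the divisions), against -0.476 undivided and -0.0206 in 100 simulations of unchanged groups. The matching r was -0.542 undivided, against -0.503 (-0.528 to -0.476) in the simulations, and -0.481 (-0.516 to -0.410) divided, where no array is shared.

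Adding spermidine/spermine together with EGBG raised the late differentiation genes again. The largest rises over EGBG alone were in LCE3A (at least 50.2-fold), S100A7 (6.60 ± 0.35), LCE2A (6.08 ± 0.27), LCE3C (6.06 ± 0.24, 1 of 4 EGBG), KLK6 (5.61 ± 0.30) and KPRP (5.61 ± 0.21), a keratinocyte proline-rich protein. The largest falls were in TXNIP (-5.45 ± 0.55), DAPL1 (-4.73 ± 0.34, 3 of 4 EGBG plus SDSM), COQ8A (at least 5.72-fold), RAB7B (at least 8.83-fold), a GTPase of endosomes, PIR (-3.77 ± 0.25, 3 of 4 EGBG plus SDSM), the iron-binding pirin, and the small heat shock protein HSPB3 (-3.57 ± 0.25). The question is what SDSM changes where EGBG is given.

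In the cornified envelope list 43 of 46 rose and 0 fell (the same adjusted over the list alone), with a median of 3.66 (3.15 at bounds) and camera adjusted p = 1.27e-31. Barrier lipid synthesis had a median of 1.66 (1.503 at bounds) and camera adjusted p = 5.09e-13. In this list, 22 of 25 rose and 0 fell (the same adjusted over the list alone), CYP4F22 (4.58 ± 0.25, 3 of 4 EGBG) and the lipid transporter ABCA12 (2.82 ± 0.18) among them. Proteases and inhibitors had a median of 2.22 (2.07 at bounds) and camera adjusted p = 4.15e-15. Gene by gene, 21 of 24 rose and 0 fell (the same adjusted over the list alone), with ASPRV1 (4.20 ± 0.20) and SPINK7 (3.67 ± 0.26, 3 of 4 EGBG). Stress keratins and antimicrobial genes had a median of 2.28 and camera adjusted p = 3.16e-09. Counted singly, 15 of 19 rose and 0 fell (the same adjusted over the list alone), with DEFB103A (5.31 ± 0.40), a beta-defensin, IL36G (4.57 ± 0.29, 1 of 4 EGBG) and IL36RN (3.99 ± 0.18). Spinous genes did not pass as a list (median 0.20 (0.17 at bounds), adjusted p = 0.137), although CALML5 rose (3.89 ± 0.31), and neither did basal genes (median 0.15, adjusted p = 0.289).

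Cytokines and NF-kB targets had a median of 1.92 (1.37 at bounds) and camera adjusted p = 7.33e-08, adjusted p = 0.058 with an estimated correlation. Of its members, 15 of 18 rose and 0 fell (the same adjusted over the list alone). The neutrophil attractant CXCL8 rose at least 15.7-fold and PTGS2 (4.54 ± 0.33, 2 of 4 EGBG) and IL1A (2.99 ± 0.29) rose with it. Immediate early genes had a median of 1.15 (1.11 at bounds) and camera adjusted p = 2.12e-09, adjusted p = 0.058 with an estimated correlation. By gene, 22 of 28 rose and 1 fell (23 and 1 adjusted over the list alone), PHLDA1 (4.16 ± 0.22) and HBEGF (2.78 ± 0.34) included. Metallothioneins had a median of 2.18 and camera adjusted p = 0.000559, with MT1E (3.01 ± 0.22) up. NRF2 targets went down, with a median of -1.36 and camera adjusted p = 1.89e-05, adjusted p = 0.058 with an estimated correlation. Counted singly, 2 of 21 rose and 18 fell (the same adjusted over the list alone). PIR, CBR1 (-3.16 ± 0.25, 2 of 4 EGBG plus SDSM) and AKR1B10 (-2.68 ± 0.27, 3 of 4 EGBG plus SDSM) fell and HMOX1 (3.87 ± 0.27) rose. The interferon list did not pass (median -0.12 (0.00 at bounds), adjusted p = 0.728), with SAMD9 (2.79 ± 0.18) higher and HERC5 (-3.33 ± 0.21, 1 of 4 EGBG plus SDSM) and TAP1 (-2.12 ± 0.19) lower.

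AMD1 fell (-1.45 ± 0.32, adjusted p = 0.000527), and AZIN1 (-1.56 ± 0.15) and SRM (-0.69 ± 0.17) fell with it. ODC1 (0.85 ± 0.19), OAZ1 (1.15 ± 0.13), SAT1 (0.75 ± 0.13) and ARG1 (5.24 ± 0.26) rose, SMOX rose at least 1.24-fold, detected on 2 of 4 EGBG plus SDSM arrays, SMS was at 0.32 ± 0.22 without passing, and PAOX was undetected in both groups. The polyamine list as a whole did not pass (median 0.18 (0.04 at bounds), adjusted p = 0.471).

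Between these groups 6218 features passed, 2694 higher (1309 at least 2-fold) and 3524 lower (1104 at least 2-fold), and 13 of the 28 lists passed, 9 higher and 4 lower, and the same 5 as for EGBG held with an estimated correlation. The share of higher calls was 43.3%, but 53.7% with median scaling, 24% without normalization and 53.5% in the authors' table, and the median of all genes moved by 0.11 with median scaling and by -0.36 without normalization.

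Set against day 6 cells without any compound, the cornified envelope, protease and cytokine lists were higher with EGBG and SDSM and the interferon list lower, none of them with an estimated correlation. The largest rises were in DEFB103B (3.46 ± 0.33) and DEFB103A (3.15 ± 0.40), the thyroid hormone deiodinase DIO2 (3.16 ± 0.27), S100A7A (at least 4.39-fold), TAGLN3 (at least 7.21-fold) and CXCL8 (3.03 ± 0.50, 3 of 4 day 6). The largest falls were in DAPL1 (-2.80 ± 0.34, 3 of 4 EGBG plus SDSM), the galectin LGALS7B (-2.40 ± 0.68), HSPB3 (-2.30 ± 0.25), PSAT1 (-2.19 ± 0.51), MX1 (-2.08 ± 0.37), an antiviral GTPase, and RAB7B (at least 2.48-fold). This comparison holds SDSM's own effect and any remnant of EGBG's.

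Cornified envelope genes had a median of 0.54 and camera adjusted p = 2.01e-08, adjusted p = 0.121 with an estimated correlation. By gene, 20 of 46 rose and 2 fell (22 and 2 adjusted over the list alone), TCHHL1 (2.97 ± 0.31, 1 of 4 day 6), a relative of trichohyalin, and LCE2A (2.53 ± 0.27) rising most. Proteases and inhibitors had a median of 0.41 and camera adjusted p = 6.21e-06, adjusted p = 0.0936 with an estimated correlation, with 10 of 24 higher, such as KLK6 (2.10 ± 0.30) and ASPRV1 (1.33 ± 0.20), and 0 lower. Cytokines and NF-kB targets had a median of 0.62 (0.50 at bounds) and camera adjusted p = 8.21e-06, adjusted p = 0.142 with an estimated correlation. In this list, 9 of 18 rose and 0 fell (10 and 0 adjusted over the list alone), IL24 (1.60 ± 0.26, 2 of 4 day 6) among them. In the interferon list 1 of 32 rose and 18 fell (1 and 22 adjusted over the list alone), with a median of -0.77 (-0.26 at bounds) and camera adjusted p = 2.01e-08, adjusted p = 0.169 with an estimated correlation. IFITM1 (-1.70 ± 0.45), IFI44 (-1.55 ± 0.26, 1 of 4 EGBG plus SDSM) and IFIT1 (-1.53 ± 0.35, 1 of 4 EGBG plus SDSM) fell besides MX1. Amino acid response genes had a median of -0.64 (-0.58 at bounds) and camera adjusted p = 6.21e-06, adjusted p = 0.294 with an estimated correlation. Gene by gene, 1 of 33 rose and 13 fell (1 and 16 adjusted over the list alone), PHGDH (-1.74 ± 0.24) of serine synthesis and ASNS (-1.71 ± 0.40) falling. NRF2 targets had a median of -0.32 and camera adjusted p = 0.000144, adjusted p = 0.121 with an estimated correlation. Counted singly, 1 of 21 rose and 7 fell (the same adjusted over the list alone), AKR1B10 (-2.002 ± 0.27, 3 of 4 EGBG plus SDSM) and PIR (-2.001 ± 0.25, 3 of 4 EGBG plus SDSM) lowest. Stress keratins and antimicrobial genes did not pass as a list (median 0.01 (0.00 at bounds), adjusted p = 0.327). Spinous genes did not pass (median -0.26, adjusted p = 0.119), nor did any of the 19 measured members on its own. AZIN1 fell (-0.85 ± 0.15), AMD1 was at -0.19 ± 0.32 and ODC1 at -0.39 ± 0.19, and neither of these passed, nor did the list (median -0.19 (-0.06 at bounds), adjusted p = 0.235). SRM (-0.06 ± 0.17), SMS (0.19 ± 0.22), SAT1 (0.25 ± 0.13), OAZ1 (0.32 ± 0.13) and SMOX (0.15 ± 0.21, 2 of 4 EGBG plus SDSM and 2 of 4 day 6) did not pass either.

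Relative to day 6 alone, 1994 features differed, 1059 higher (261 at least 2-fold) and 935 lower (157 at least 2-fold). There were 946 without day 6 replicates 1 and 3, the arrays with the lowest weights, and 851 when only these groups were fitted. The share of higher calls was 53.1%, against 68.9% with median scaling and 10% without normalization, where the median of all genes moved by 0.12 and -0.36. Of the lists 13 passed, 8 higher and 5 lower, and 0 with an estimated correlation. The calls that ended without 1 array were those of LGALS7B without day 6 replicate 1 or 3 (adjusted p up to 0.073).

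Of the 4736 genes EGBG changed, 3959 (83.6%) moved back when SDSM was added, past the threshold and against the EGBG effect. Another 13 moved further. Moving back or past day 6 may also be an SDSM effect needing no EGBG. Both steps share the EGBG arrays, which alone favours moving back. With the EGBG arrays divided 2 and 2 between choosing and measuring, a check chosen after this result was seen, 65.4% to 82.1% moved back over the 6 divisions (2765 to 2934 genes) and 5 to 77 genes moved further. Of the 1476 that EGBG changed at least 2-fold, 1405 (95.2%) moved back. Against day 6 alone, 292 (6.17%) were still past the threshold in the direction of EGBG, and 807 (17%) had passed on the opposite side. The 292 became 97 when only the groups compared were fitted and 153 without day 6 replicates 1 and 3. Across the 4736 genes, the slope of the remaining change on the EGBG change was -0.14, and with day 6 arrays divided between choosing and measuring it was -0.14 (2985 genes) and -0.18 (3241 genes). Genes that had moved back include S100A7 (-5.70 ± 0.35 with EGBG and 0.89 ± 0.35 with EGBG and SDSM, against day 6) and FLG (-2.93 ± 0.30 and 0.46 ± 0.30).

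With spermidine/spermine alone, the cornified envelope and protease lists were higher and the interferon list lower, none of them with an estimated correlation. The largest rises were in TCHHL1 (3.79 ± 0.31, 1 of 4 day 6), DEFB103B (3.61 ± 0.33), S100A7A (at least 5.88-fold), DIO2 (3.47 ± 0.27), GABBR2 (at least 5.91-fold), a subunit of the GABA-B receptor, and the pentraxin NPTX1 (at least 4.80-fold). The largest falls were in DAPL1 (-3.36 ± 0.34, 3 of 4 SDSM), TXNIP (-3.21 ± 0.55), HSPB3 (-2.88 ± 0.25, 3 of 4 SDSM), MX1 (-2.55 ± 0.37), IFITM1 (-2.35 ± 0.45), which blocks viral entry, and PIR (-2.25 ± 0.25, 2 of 4 SDSM). The question is what added spermidine/spermine does when AMD1 is not inhibited.

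Cornified envelope genes had a median of 0.64 and camera adjusted p = 5.47e-11, adjusted p = 0.103 with an estimated correlation. Of its members, 24 of 46 rose and 1 fell (25 and 2 adjusted over the list alone), LCE3A (2.74 ± 0.30) and LCE1B (2.41 ± 0.26) among them. Proteases and inhibitors had a median of 0.55 and camera adjusted p = 5.24e-07, adjusted p = 0.093 with an estimated correlation. By gene, 13 of 24 rose and 0 fell (14 and 0 adjusted over the list alone), with KLK6 (2.57 ± 0.30) and KLK13 (1.78 ± 0.17). Immediate early genes had a median of 0.51 and camera adjusted p = 7.64e-06, adjusted p = 0.169 with an estimated correlation. In this list, 11 of 28 rose and 0 fell (16 and 0 adjusted over the list alone), EGR3 (1.63 ± 0.26) and IER3 (1.38 ± 0.26) included. Stress keratins and antimicrobial genes did not pass as a list (median -0.01 (0.00 at bounds), adjusted p = 0.233).

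In the interferon list 2 of 32 rose and 20 fell (2 and 22 adjusted over the list alone), with a median of -0.76 (-0.32 at bounds) and camera adjusted p = 4e-08, adjusted p = 0.169 with an estimated correlation. OAS2 (-2.11 ± 0.32, 1 of 4 SDSM), which senses double-stranded RNA, and IFI27 (-2.11 ± 0.59) fell besides MX1 and IFITM1. Within the polyamine pathway AZIN1 fell (-0.89 ± 0.15), OAZ1 rose (0.37 ± 0.13) and MAT2A (1.62 ± 0.35), which makes the substrate of AMD1, rose. AMD1 was at 0.06 ± 0.32 (adjusted p = 0.907) and ODC1 at -0.27 ± 0.19, neither past the threshold, and SRM (-0.36 ± 0.17), SMS (0.21 ± 0.22), SAT1 (0.21 ± 0.13) and SMOX (0.42 ± 0.21, 2 of 4 day 6) did not pass. Their list did not pass either (median -0.18 (0.01 at bounds), adjusted p = 0.512).

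Counted over all features, 3083 passed with SDSM, 1500 higher (416 at least 2-fold) and 1583 lower (276 at least 2-fold). There were 1930 without day 6 replicates 1 and 3, and 1944 when only these groups were fitted. The share of higher calls was 48.7%, against 66.7% with median scaling and 23.3% without normalization, where the median of all genes moved by 0.15 and -0.22. Of the lists 12 passed, 8 higher and 4 lower, and 0 with an estimated correlation. Leaving out 1 array ended the calls of OAZ1 without day 6 replicate 1 or 2 or SDSM replicate 1, 2, 3 or 4 (adjusted p up to 0.103).

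Putrescine, the precursor of spermidine, changed fewer features than SDSM did and lowered ODC1. The largest rises were in TCHHL1 (2.72 ± 0.31, 1 of 4 day 6), STC2 (2.65 ± 0.44), the stress-induced stanniocalcin, NPW (at least 4.29-fold), which encodes a neuropeptide, KCTD12 (at least 4.68-fold), PSG7 (2.43 ± 0.31, 2 of 4 day 6) and CCNA1 (2.43 ± 0.28), a cyclin. The largest falls were in DAPL1 (at least 12.8-fold), TXNIP (-4.02 ± 0.55), SPINK6 (-3.34 ± 0.34, 3 of 4 PUT), an inhibitor of kallikreins, IFI27 (-2.72 ± 0.59), the gelatinase MMP9 (-2.51 ± 0.51, 1 of 4 PUT) and PIK3IP1 (-2.46 ± 0.31, 3 of 4 PUT). ODC1 fell (-1.51 ± 0.19, adjusted p = 1.09e-05), AZIN1 fell (-1.93 ± 0.15, but -1.05 on a less bright probe) and AMD1 was higher (1.01 ± 0.32, adjusted p = 0.0322). The comparison asks what the precursor does on its own, with AMD1 not inhibited.

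MAT2A rose (1.64 ± 0.35), whereas SRM (-0.06 ± 0.17), SMS (0.10 ± 0.22), SAT1 (0.36 ± 0.13), OAZ1 (0.27 ± 0.13) and SMOX (-0.13 ± 0.21, 2 of 4 PUT and 2 of 4 day 6) did not pass, and the polyamine list did not pass (median 0.15, adjusted p = 0.792). Amino acid response genes had a median of 0.52 (0.51 at bounds) and camera adjusted p = 6.97e-06, adjusted p = 0.392 with an estimated correlation. Counted singly, 13 of 33 rose and 0 fell (15 and 0 adjusted over the list alone), with STC2 and the amino acid transporter SLC7A5 (1.16 ± 0.24).

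Cornified envelope genes had a median of 0.56 and camera adjusted p = 0.000128, adjusted p = 0.392 with an estimated correlation. By gene, 20 of 46 rose and 2 fell (23 and 6 adjusted over the list alone), with LCE1B (2.36 ± 0.26) and LCE1C (1.94 ± 0.25) up. Spinous genes had a median of -0.45 and camera adjusted p = 0.00449, adjusted p = 0.392 with an estimated correlation. In this list, 0 of 19 rose and 4 fell (the same adjusted over the list alone), CALML5 (-1.07 ± 0.31) falling most. In the interferon list 1 of 32 rose and 9 fell (1 and 15 adjusted over the list alone), with a median of -0.50 (-0.25 at bounds) and camera adjusted p = 5.17e-05, adjusted p = 0.392 with an estimated correlation, OASL (-1.22 ± 0.26, 1 of 4 PUT) and IFI44 (-1.17 ± 0.26, 1 of 4 PUT) falling. Stress keratins and antimicrobial genes did not pass as a list (median -0.25, adjusted p = 0.0899), with S100A12 (-1.86 ± 0.26) and KRT6C (-1.77 ± 0.41) lower and DEFB103A (1.66 ± 0.40) higher.

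With putrescine 2015 features passed, 1164 higher (244 at least 2-fold) and 851 lower (147 at least 2-fold), but 1194 without PUT replicate 1, 1292 without day 6 replicate 1, 1328 without PUT replicate 4 and 1124 without day 6 replicates 1 and 3. The share of higher calls was 57.8%, against 75.1% with median scaling and, of 1024 calls, 27.8% without normalization, where the median of all genes moved by 0.13 and -0.21. Of the lists 12 passed, 6 higher and 6 lower, and 0 with an estimated correlation. The calls that ended without 1 array were those of CALML5 without day 6 replicate 1 or PUT replicate 1 (adjusted p up to 0.0932) and AMD1 without PUT replicate 1, 2, 3 or 4 or day 6 replicate 2 or 3 (adjusted p up to 0.113).

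The compounds differed in ODC1 and in protease, barrier lipid and autophagy genes. Spermidine and spermine carry aminopropyl groups that putrescine lacks, and both treatments were given at 1 mM from day 3. Compared with putrescine, SDSM gave higher S100A7A (at least 5.86-fold), SPINK6 (2.97 ± 0.34, 3 of 4 PUT), SPINK1 (2.72 ± 0.45), HSPA6 (at least 2.67-fold), LRRC20 (2.44 ± 0.19) and SPINK7 (2.38 ± 0.26). It gave lower CCNA1 (-2.54 ± 0.28), TCN1 (at least 2.57-fold), a carrier of cobalamin, STC2 (-2.01 ± 0.44), WNT10A (-1.84 ± 0.31), CMBL (-1.78 ± 0.18) and GPX8 (-1.78 ± 0.24). The comparison asks whether the precursor and the products act alike.

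ODC1 was higher with SDSM than with PUT by 1.24 ± 0.19 (95% interval 0.85 to 1.64), and AMD1 was lower at -0.94 ± 0.32 (-1.60 to -0.28). AZIN1 was higher by 1.04 ± 0.15 (0.74 to 1.34) on the probe used, but a less bright AZIN1 probe was at 0.33 and did not pass, so the probes disagree. SRM was at -0.30 ± 0.17 (-0.65 to 0.06), SMS at 0.11 ± 0.22 (-0.35 to 0.58), SAT1 at -0.15 ± 0.13 (-0.42 to 0.11), OAZ1 at 0.10 ± 0.13 (-0.16 to 0.36) and SMOX at 0.55 ± 0.21, detected on 2 of 4 PUT arrays (0.12 to 0.98), and none of these passed. The polyamine list as a whole did not pass (median -0.15 (-0.11 at bounds), adjusted p = 0.635).

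Proteases and inhibitors had a median of 0.56 and camera adjusted p = 2.33e-09. Gene by gene, 11 of 24 rose and 0 fell (14 and 0 adjusted over the list alone), KLK13 (1.34 ± 0.17) among them. Barrier lipid synthesis had a median of 0.45 and camera adjusted p = 7.54e-06. Counted singly, 11 of 25 rose and 1 fell (13 and 1 adjusted over the list alone), with PNPLA1 (1.48 ± 0.18), needed for acylceramides, and CYP4F22 (1.09 ± 0.25). Autophagy and lysosome genes had a median of 0.45 and camera adjusted p = 2.28e-06. Of its members, 10 of 27 rose and 1 fell (12 and 1 adjusted over the list alone), led by GPNMB (1.76 ± 0.31). Cornified envelope genes had a median of 0.39 and camera adjusted p = 5.96e-06, adjusted p = 0.218 with an estimated correlation. By gene, 14 of 46 rose and 3 fell (15 and 3 adjusted over the list alone), LCE3A (2.37 ± 0.30) included. Stress keratins and antimicrobial genes had a median of 0.48 and camera adjusted p = 0.000221, adjusted p = 0.147 with an estimated correlation, with S100A7 (2.14 ± 0.35) and S100A12 (2.03 ± 0.26) higher.

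Lower with SDSM than with PUT was the amino acid response list, with a median of -0.44 (-0.39 at bounds) and camera adjusted p = 0.000602, adjusted p = 0.449 with an estimated correlation, where 1 of 33 rose and 10 fell (1 and 15 adjusted over the list alone). Interferon genes had a median of -0.39 (-0.01 at bounds) and camera adjusted p = 0.00441, adjusted p = 0.474 with an estimated correlation. IFITM1 (-1.75 ± 0.45) and MX1 (-1.44 ± 0.37) were lower and OASL (2.19 ± 0.26, 1 of 4 PUT) higher. By gene, 1 of 32 rose and 12 fell (1 and 15 adjusted over the list alone).

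There were 2069 features past the threshold between the compounds, 862 higher with SDSM (208 at least 2-fold) and 1207 lower (141 at least 2-fold), and 874 without normalization between arrays. Of the 28 lists 15 passed, 9 higher and 6 lower, and 3 also with an estimated correlation (protease, barrier lipid and autophagy genes). For the 10080 features that did not pass, the 95% interval of the difference lay inside a 2-fold change either way for 9520, and the interval reached 0.37 to either side of the estimate at the median. Leaving out 1 array ended the calls of AMD1 without SDSM replicate 1, 2, 3 or 4 or PUT replicate 1, 2, 3 or 4 (adjusted p up to 0.101).

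Both compounds were also set against the same day 6 arrays. There were 537 features higher with both and 471 lower with both, against 143.7 and 110.9 for independent calls, and 31 moved in opposite directions. The sum of 1008 fell to 645 without day 6 replicate 1, 663 without PUT replicate 1 and 483 without day 6 replicates 1 and 3. TXNIP, DAPL1 and HSPB3 fell and TCHHL1 rose with both; HSPB3 was at -2.21 ± 0.25 with PUT and -2.88 ± 0.25, detected on 3 of 4 SDSM arrays, with SDSM. With the day 6 arrays divided between the compounds, the covariance across genes was 0.117 (0.0923 to 0.138), against 0.152 undivided and 0.0206 in 100 simulations of unchanged groups. The r across genes was 0.643 undivided, against 0.502 (0.481 to 0.527) in the simulations, and 0.439 (0.335 to 0.555) divided.

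The effect of EGBG depended on whether spermidine/spermine was present. For S100A7 the EGBG effect was higher by 5.69 ± 0.49 with SDSM than without it, and for SERPINA12 by 4.80 ± 0.33, detected on 1 of 4 EGBG arrays, for WFDC12, a protease inhibitor, by 4.47 ± 0.39, and for ARG1 by 4.32 ± 0.37. It was lower for EPCAM (-2.97 ± 0.33), PLD6 (-2.87 ± 0.29, 3 of 4 day 6 and 2 of 4 EGBG plus SDSM) and AMD1 (-1.51 ± 0.45, adjusted p = 0.02). SPRR2B, COQ8A and HERC5 were also among the largest, but each was undetected on all arrays of a group, so no value is given. This test asks whether the EGBG change is the same in both settings.

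In the cornified envelope list the difference was positive for 39 of 46 genes and negative for 0 (42 and 0 adjusted over the list alone), with median 2.86, adjusted p = 2.07e-41. Positive differences also held for barrier lipid synthesis (median 1.52, adjusted p = 2.42e-18), proteases and inhibitors (median 1.36, adjusted p = 5.82e-17), stress keratins and antimicrobial genes (median 1.58, adjusted p = 3.51e-13) and metallothioneins (median 2.37, adjusted p = 5.02e-07). Immediate early genes had median 0.72, adjusted p = 1.2e-06, adjusted p = 0.13 with an estimated correlation, cytokines and NF-kB targets median 1.22, adjusted p = 1.63e-07, adjusted p = 0.0608 with an estimated correlation, and glycolysis and hypoxia genes median 0.70, adjusted p = 9.68e-07, adjusted p = 0.0592 with an estimated correlation, with SLC2A3 at 3.37 ± 0.26. The interferon list had median 1.06, adjusted p = 2.68e-05, 0.265 with an estimated correlation. Genes stopped at background may add to that, as the list also fell with SDSM. SAMD9 was at 2.65 ± 0.25 and OAS2 at 2.17 ± 0.46 (3 of 4 EGBG and 1 of 4 SDSM). Negative differences held for ribosome biogenesis (median -0.60, adjusted p = 2.1e-05, adjusted p = 0.193 with an estimated correlation), with RRP12 at -1.67 ± 0.26, detected on 3 of 4 SDSM arrays, NRF2 targets (median -0.92, adjusted p = 0.000144, adjusted p = 0.0803 with an estimated correlation) and p53 targets (median -0.40, adjusted p = 0.00955), while HMOX1 was at 2.66 ± 0.38. For ODC1 the difference was 1.12 ± 0.27, for OAZ1 0.78 ± 0.18 and for AZIN1 -0.66 ± 0.21, all past the threshold.

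The interaction passed for 2245 features, 1181 positive (774 at least 2-fold) and 1064 negative (385 at least 2-fold), and for 1346 without normalization between arrays. Positive shares were 52.6% here and 70.4% in the authors' normalized table. Of the lists 18 passed, 13 positive and 5 negative, and 6 also with an estimated correlation (cornified envelope, barrier lipid, protease, stress keratin, metallothionein and p53 target genes). The calls that ended without 1 array were those of AMD1 without EGBG replicate 1 or EGBG plus SDSM replicate 1 (adjusted p up to 0.0528) and AZIN1 without day 6 replicate 2 or EGBG replicate 3 or EGBG plus SDSM replicate 4 (adjusted p up to 0.0639).

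**Figure D2:**
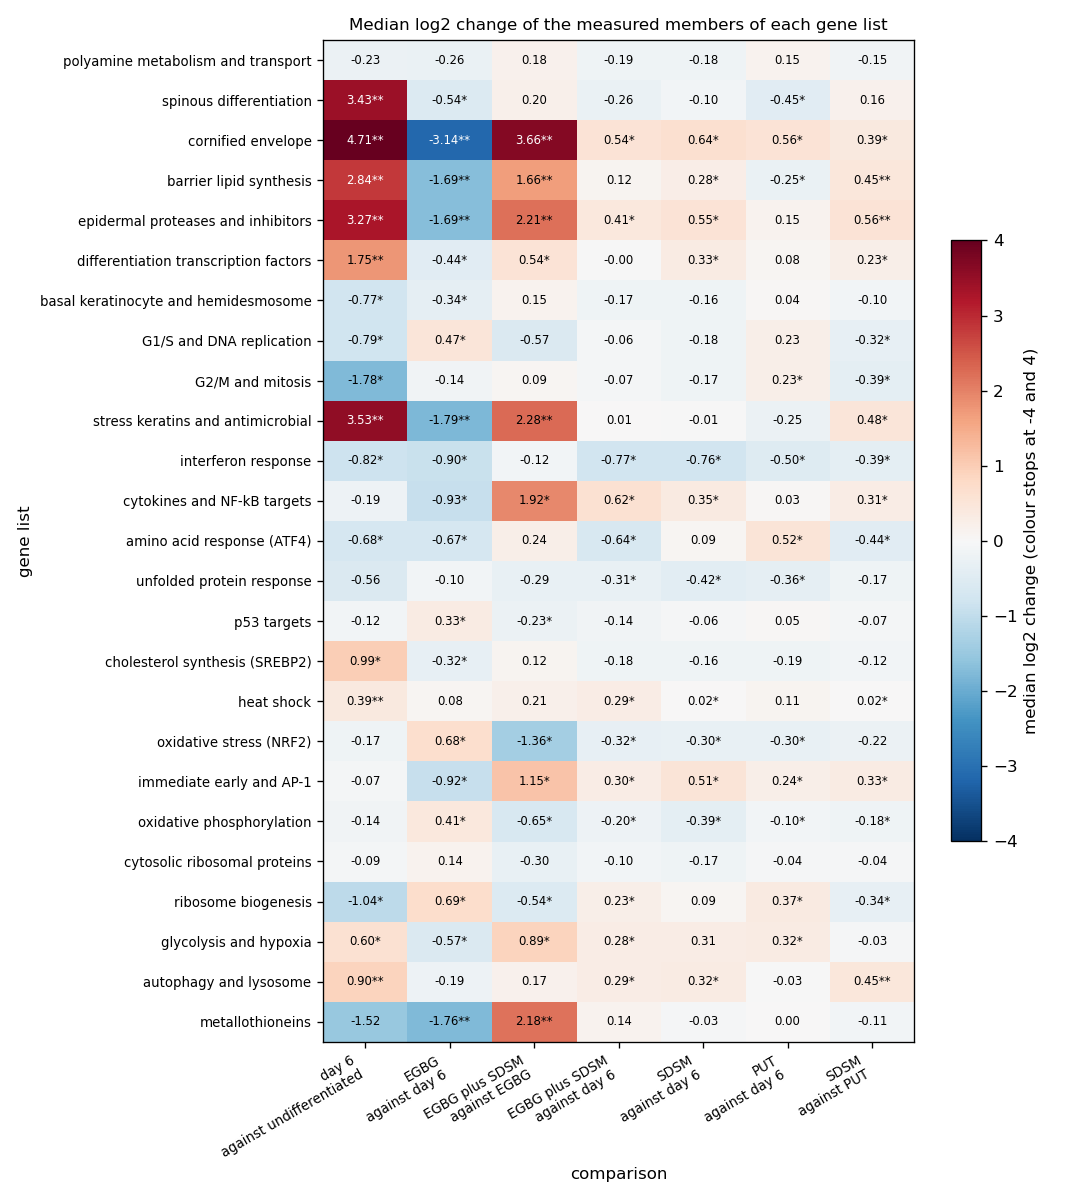
Median log2 change of each gene list with at least 6 measured members (lines) in 7 comparisons (columns), with the colour scale stopping at a log2 change of 4 either way; 1 star marks camera adjusted p under 0.05 with the preset correlation and a further star the same with an estimated correlation. Cornified envelope, barrier lipid and protease lists were high at day 6, low with EGBG and high again with SDSM added, and spinous genes had a median of -0.54 (-0.32 at bounds) with EGBG beside -3.14 for cornified envelope genes.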

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

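Of the tests here, those in the authors' normalized table, without day 6 replicates 1 and 3, with the residual axis as a covariate, of interferon genes with EGBG alone and at bounds, of the cornified minus spinous difference and of the ratio of EGBG to differentiation changes were chosen only after the results were seen. The EGBG effect differed with and without spermidine/spermine for 2245 features, by the interaction test. In the 2-group fits, the labelled division gave the most features of the 35 in each comparison. With 35 divisions, chance is argued against for these fits but not excluded. The labelled division and the highest other gave 6413 and 0 for day 6, 3728 and 272 for EGBG, 5877 and 0 for SDSM added to EGBG, 851 and 0 for EGBG plus SDSM against day 6, 1944 and 0 for SDSM, 1426 and 0 for PUT, and 2327 and 0 for SDSM against PUT. The division with 272 set replicates 1 and 3 of day 6 and EGBG against replicates 2 and 4, a structure shared across groups.

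Interferon response genes had a median of -0.76 with SDSM against day 6 alone, or -0.32 with the 11 of 32 genes undetected in 1 group at their bounds and the 3 undetected in both at 0 (camera adjusted p = 4e-08, from 6.77e-14 to 0.169 over the alternatives, the highest with an estimated correlation). The day 6 arrays of lowest weight are argued against as the whole source, since the median was -0.826 without them (adjusted p = 1.03e-07), although -0.308 at bounds; the residual axis as a covariate cannot move a group difference, so its -0.763 decides nothing. Whether the fall needs an added polyamine stays open, since EGBG alone gave -0.90 (-0.40 at bounds) against the same day 6 arrays, a value seen before that test was framed. A raised interferon state in the day 6 cultures, to which each of these comparisons refers, could give the same pattern and stays open, although the list was also lower at day 6 than in undifferentiated cells (median -0.82, or -0.75 at bounds). A response to polyamine balance is the biological explanation the design offers and was not tested apart from these.

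Cornified envelope genes had a median of 0.64 with SDSM against day 6 alone (camera adjusted p = 5.47e-11, from 6.07e-18 to 0.103 over the alternatives, the highest with an estimated correlation). The day 6 arrays of lowest weight are argued against as the source, since the median was 0.608 without them (adjusted p = 1.18e-11), while the 0.635 with the residual axis decides nothing. Probes that cannot separate LCE and SPRR genes are argued against as the whole source, since the 21 members outside these families had a median of 0.59 (adjusted p = 1.08e-05), beside 1.47 for the 25 within them. In the authors' normalized table, where values stop at a floor, the median was 0 and the list did not pass (adjusted p = 0.0852). A stimulation of late differentiation by spermidine/spermine may underlie the pattern, a hypothesis that the correlation among the genes leaves open.

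EGBG lowered cornified envelope genes by more than spinous genes, with medians of -3.14 and -0.54, the latter -0.32 at bounds and -0.28 without day 6 replicate 1; per array, the mean of the first list minus that of the second was lower by a log2 of 2.08 with EGBG (exact permutation p = 0.0286, the least possible with 70 divisions). Saturation of bright spinous probes is argued against, since the 13 spinous members under a signal of 20000 had a median of -0.585 and the 6 others -0.43. Saturation of bright probes in general is argued against by the 13 cornified members at least as bright as the median spinous one, at -3.234. Whether EGBG undid the calcium response by one share for every gene cannot be told apart from a stage-specific effect: the ratios of EGBG to differentiation medians were -0.158 for spinous and -0.666 for cornified genes and differed by 0.508, but the ranges of the middle genes overlapped (-0.574 to 0.003 and -0.825 to -0.494). A block late in differentiation may be the biological explanation and stays open.

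Among 33 genes, 28 lists and 3 array measures, 384 groups of 4 arrays were looked at for an array far from the others; 22 had one, 11 for lists, 11 for genes and 0 for array measures. Chance alone gives about 1 in 20 groups such an array. Values are log2 signals, with the range of the others of the group. In undifferentiated cells these were polyamine genes on replicate 4 at 9.732 (9.556 to 9.584), proteases on replicate 1 at 7.373 (7.618 to 7.65), SAT1 on replicate 1 at 14.95 (14.67 to 14.71), and on replicate 2 FLG at 7.126 (5.321 to 5.573), KRT1 at 7.175 (5.48 to 5.75) and SERPINA12 at 5.403 (5.26 to 5.272). At day 6 they were mitosis genes on replicate 4 at 6.972 (7.066 to 7.082) and, on replicate 3, oxidative phosphorylation at 11.81 (11.44 to 11.44), FLG at 13.59 (14.48 to 14.59) and CDC20 at 7.293 (7.995 to 8.084). With EGBG they were p53 targets at 9.136 (9.23 to 9.241) and SMS at 10.15 (9.186 to 9.345), both on replicate 3. With EGBG and SDSM they were DNA replication genes on replicate 1 at 7.812 (8.073 to 8.106), ribosomal proteins on replicate 3 at 13.55 (13.33 to 13.34) and CRCT1 on replicate 2 at 13.51 (14.16 to 14.19). With SDSM they were SPRR2B at 9.917 (10.23 to 10.28) and CRCT1 at 14.23 (14.56 to 14.59) on replicate 2 and LCE3A on replicate 3 at 12.67 (12.87 to 12.91). With PUT they were mitosis genes on replicate 1 at 7.521 (7.283 to 7.298), stress keratins at 11.34 (11.48 to 11.5) and the unfolded protein response at 9.977 (9.758 to 9.777) on replicate 2, and autophagy genes on replicate 4 at 10.31 (10.19 to 10.2).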

How the results depend on the processing

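Of the tests here, the authors' normalized table, leaving out day 6 replicates 1 and 3, and the residual axis as a covariate were chosen only after the results were seen. No named gene, list or summary past the threshold turned its direction under any alternative run. Cornified envelope medians became 0 in the authors' normalized table, where values stop at a floor. All 23 summary results kept their side of the threshold or stayed within 1.5 times with all detected probes, as did the 20 run with array weights. With each array left out in turn, 187 of 192 did, and counts of features moved within 6555 to 6900 for day 6, 4167 to 4802 for EGBG, 5617 to 6083 for SDSM added to EGBG, 1365 to 2114 for EGBG plus SDSM against day 6, 2441 to 3264 for SDSM, 1438 to 1886 for SDSM against PUT and 1939 to 2387 for the interaction. The range was wider for PUT, from 1194 without PUT replicate 1 to 2070 without day 6 replicate 3, and for features shared by SDSM and PUT, from 645 without day 6 replicate 1 to 1157 without SDSM replicate 3. Of 322 named gene values, 303 kept sign and call without normalization between arrays and 313 with median scaling. The authors' normalized table kept 234, and 84 no longer passed.

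The results that changed are given by setting, and the cause was not tested except where stated. Without background correction the covariance of EGBG and differentiation effects, with day 6 arrays divided, was -0.533 and that of SDSM and PUT effects 0.139; with median scaling the first was -0.469 and with detection in a whole group -0.486. The series matrix without normalization gave 1024 features for PUT, 874 for SDSM against PUT, 1346 for the interaction, 582 shared by SDSM and PUT, and covariances of -0.535 and 0.138. There the median of all genes moved by -0.12 at day 6 and by -0.15 for the interaction. With no detection filter the covariances were -0.146 and 0.039, over 37240 features in place of 12149. With only the groups compared in the fit, and so fewer arrays to estimate the spread, 851 features passed for EGBG plus SDSM against day 6 and 1944 for SDSM, and 97 were still past the threshold after SDSM was added to EGBG. An estimated correlation left 8 lists for day 6, 5 for EGBG, 5 for SDSM added to EGBG, 0 for EGBG plus SDSM against day 6, 0 for SDSM, 0 for PUT, 3 for SDSM against PUT and 6 for the interaction. The authors' normalized table gave 1298 features for EGBG plus SDSM against day 6, 1213 for PUT, 1347 for SDSM against PUT, 640 shared by SDSM and PUT, and covariances of -0.362 and 0.137. Without day 6 replicates 1 and 3, which leaves fewer arrays, the counts were 946 for EGBG plus SDSM against day 6, 1930 for SDSM, 1124 for PUT, 153 still past the threshold and 483 shared. The residual axis gave 3129 for PUT, 477 still past the threshold and 1777 shared; it comes from the same residuals, so it cannot move a group difference and its p-values are too small.

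With a replicate block all 20 summary results run stayed within 1.5 times, with 7425 features for day 6, 5285 for EGBG, 6662 for SDSM added to EGBG, 2563 for EGBG plus SDSM against day 6, 3696 for SDSM, 2741 for PUT, 2518 for SDSM against PUT and 2641 for the interaction; 2 of 322 named gene values came to pass and 0 ceased to. The labels give each group numbers 1 to 4 without saying that they pair the arrays. Deviations of same-numbered arrays from their group means correlated at over 0.1 in 43 of 60 pairs (-0.257 to 0.571, median 0.230, against -0.0636 for different numbers), and 18 of 24 arrays matched their own number best, a hint from the data and not the design. Divided covariances were not run with arrays left out, array weights, the block or the residual axis. The limit set by signal over background is at dim genes, where a group without detection gives only a bound.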

Other observations

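Of the tests here, leaving out day 6 replicates 1 and 3 was chosen only after the results were seen. With spermidine/spermine added to EGBG, further lists also passed against EGBG alone, none of them with an estimated correlation. Among p53 targets, 3 of 24 rose and 11 fell (the same adjusted over the list alone), with a median of -0.23 and camera adjusted p = 0.034, adjusted p = 0.0674 with an estimated correlation; SESN1 (at least 6.18-fold), a sestrin, RRM2B (at least 3.91-fold), a subunit of ribonucleotide reductase, and SPATA18 (-2.68 ± 0.22, 3 of 4 EGBG plus SDSM) fell, and TP53I3 rose (at least 5.63-fold). Of the ribosome biogenesis genes 0 of 23 rose and 15 fell (0 and 17 adjusted over the list alone), with a median of -0.54 and camera adjusted p = 0.005, adjusted p = 0.423 with an estimated correlation, RRP12 (-1.78 ± 0.18), WDR12 (-1.23 ± 0.18) and DKC1 (-1.10 ± 0.13), the pseudouridine synthase dyskerin, falling most. In the list of differentiation transcription factors 11 of 22 rose and 3 fell (the same adjusted over the list alone), with a median of 0.54 (0.41 at bounds) and camera adjusted p = 0.005, adjusted p = 0.294 with an estimated correlation; PRDM1 (3.23 ± 0.23), RORA (2.08 ± 0.21) and KLF4 (2.05 ± 0.21) rose and NOTCH1 fell (-2.24 ± 0.30).

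The unfolded protein response list was lower with SDSM, with PUT and with EGBG plus SDSM than at day 6 alone, in none of these with an estimated correlation. With SDSM, 2 of 18 rose and 9 fell (2 and 10 adjusted over the list alone), with a median of -0.42 (-0.39 at bounds) and camera adjusted p = 0.00662, adjusted p = 0.142 with an estimated correlation; CRELD2 (-1.40 ± 0.20) and the disulfide isomerase PDIA6 (-1.29 ± 0.34, 1 of 4 SDSM; adjusted p = 0.173 without day 6 replicates 1 and 3) fell, and EDEM1 rose (1.04 ± 0.17). With PUT, 1 of 18 rose and 6 fell (the same adjusted over the list alone), with a median of -0.36 and camera adjusted p = 0.00559, adjusted p = 0.392 with an estimated correlation, CRELD2 (-1.15 ± 0.20) falling most. With EGBG and SDSM, 1 of 18 rose and 7 fell (2 and 8 adjusted over the list alone), with a median of -0.31 (-0.18 at bounds) and camera adjusted p = 0.00272, adjusted p = 0.121 with an estimated correlation; the chaperone HSPA5 (-1.15 ± 0.28) fell with CRELD2 (-1.07 ± 0.20). These comparisons use the same day 6 arrays, so they are not independent.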
